A study of Mus musculus with 2 samples.

How the data were processed

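The samples were 2 biological replicates of H3K4me2 chromatin immunoprecipitation from hindbrain of mouse embryos (strain B6NCrl, embryonic day 12.5), pooled from 120 and 88 embryos with both sexes mixed, per the labels. They formed a single group, so the comparisons were between the replicates and between sets of genes or sites within the tissue. The labels name a size range of 300 to 500 and a possible control experiment, which was not analysed here. The authors deposited 4 peak lists on the mm10 assembly: 1 for each replicate, derived from that replicate's alignments and a further file, 1 pooled from both replicates, and 1 of replicated peaks, derived from the other lists, per the file descriptions deposited with the samples. The aligner, the peak caller, its thresholds and the rule for a replicated peak are not given in the sources used here.

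In each list the authors gave a fold enrichment, a ratio with 1 value per peak, whose background is not given in the sources used here. The authors also deposited for each peak a −log10 p and a −log10 q and the offset of its summit. These are the peak's own values and were used only to describe, rank or filter peaks within a list. Values and positions of all 36125 replicated peaks were identical to peaks of the pooled list. Of these, 32743 (90.6%) were matched in both replicate lists at 50% of either peak; the other 3382 had a median fold enrichment of 3.14 and reached at most 7.79. A replicated peak was thus not always a peak of each replicate list. No list gives read counts, so the depth is unknown, and intervals on shares cover the counting of peaks or genes only. No peaks were shared with identical coordinates and values between the replicate lists (0), so they were counted as separate samples.

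Analyses used chromosomes 1 to 19 and X, with sequence of GRCm38.p6, the build that mm10 names, and the basic GENCODE vM21 annotation. Every peak ended within its chromosome. A peak was shared when at least 50% of either peak was overlapped. Promoters were the 1 kb on either side of the starts of coding transcripts (41162 starts of 21668 genes). A gene's fold enrichment was that of its highest promoter peak. Domains were peaks joined within 1 kb, and a gene's width was that of the widest domain at its promoter, or 0 bp. Hox coverage was the number of bases under peaks within 2.5 kb of the best covered start. Distal peaks had summits over 2.5 kb from every coding start and were counted within 100 kb of the gene's 5' end. Promoter CpG content was the highest observed to expected CpG ratio over the gene's starts, within 500 bp on either side.

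The 24 gene lists, 15 consensus motifs, tests, alternatives and the rule for naming genes were fixed before the data were examined. The lists held 373 entries, some genes in more than 1 list, plus all odorant receptor symbols, and 1 entry (Ahsp) was not in the annotation. The rule named at most 8 Hox genes, the 4 with most and the 4 with fewest covered bases. From each other list it named up to 3 members with the highest fold enrichment. It also named up to 3 members without a promoter peak, in alphabetical order. Beyond the lists it named the 20 genes with the widest domains and the 10 with most distal peaks. Last came the 10 genes with the highest fold enrichment in the replicated list, among those with a promoter peak in both replicates. Marked shares were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment. Widths and distal counts were placed among 10000 random lists of the same size, drawn with replacement within 10 bins of CpG ratio, which describes these lists and is not a test over samples. Group differences used two-sided permutation tests with 100000 resamples over genes. Motif matches on either strand in the 300 bp around distal summits were compared with windows 5 to 50 kb away, outside all peaks and within 2 percentage points of GC; 16627 of 18743 distal peaks had such a window. Values over replicates are mean ± SD of both replicate lists.

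Alternatives changed the overlap rule, the −log10 q minimum (2 or 5), the list (pooled, or each replicate alone), the promoter window, the start sites, the joining gap, the distal window, the matching, and the width or centre of the motif window. Added after seeing the data were the replicated peaks matched in both replicate lists, the comprehensive transcripts, annotated 5' ends for Hox genes and counting each domain once. On simulated data, the overlap step recovered a planted sharing of 70% in each of its draws over 10000 peaks. Over 21668 genes, 1.5% of lists without an effect lay outside the 2.5th to 97.5th percentile of width and 0% passed the marking test. Those lists were drawn at random from all genes, without a CpG preference or shared domains. They do not show how the marking test treats CpG-rich lists, nor how either step treats neighbouring genes. Of lists of 20 genes with doubled width, all drawn from the highest CpG bin, 96% were found. The permutation test passed 4% of draws without a difference and 100% with a difference of 2 SD, over 28 values. A motif planted in 20% of 5000 windows was recovered at 19.8%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and samtools 1.23.1, and plots used matplotlib 3.10.9. Peaks on chromosome Y and on contigs were left out of the comparisons because their copies and annotation differ from the other chromosomes.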

Results

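H3K4me2 marks the promoters of active and poised genes and many distal regulatory elements. It was profiled by chromatin immunoprecipitation sequencing in mouse hindbrain at embryonic day 12.5, when the rhombomeres have formed their neuronal columns and the cerebellum is beginning to grow. Both samples were biological replicates of the same group, without any other tissue, stage or treatment. Replicate 1 was tissue pooled from 120 embryos and replicate 2 from 88 embryos, with both sexes mixed. The list of replicate 1 held 46873 peaks covering 49.2 Mb, and that of replicate 2 held 48515 peaks covering 52.2 Mb. The authors' list of pooled replicates held 51745 peaks, and their list of replicated peaks held 36125 peaks covering 53.7 Mb, or 2.10% of chromosomes 1 to 19 and X. The lists give no read counts, so the sequencing depth behind each peak is unknown. All coordinates refer to the mm10 assembly, and gene positions come from the GENCODE annotation of that assembly.

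The first comparison asked how far the replicates shared their peaks. Strong peaks were present in both lists, and the peaks found in only 1 replicate were weak and narrow. Of the replicate 1 peaks, 77% (95% Wilson interval 76.6 to 77.4%; 36064 of 46851) were shared with replicate 2. In the other direction 71.4% (71.0 to 71.8%; 34614 of 48492) were shared. Circularly shifting 1 list within each chromosome gave means of 3.00% and 2.88% over 1000 shifts, and no shift exceeded 3.62% or 3.45%. The median fold enrichment of replicate 1 peaks was 10.7 when shared and 2.93 when not, and their median widths were 938 bp and 222 bp. In 10 equal bins of fold enrichment, sharing rose from 32.4% (31.0 to 33.7%) in bin 1, the lowest, of replicate 1 to 99.3% in bin 6 and 100% in bin 10. In replicate 2 it rose from 22.9% (21.7 to 24.1%) to 98.2% and 100% in the same bins. The bases common to both lists made up 76.7% of the bases in either. Across 32682 pairs of shared peaks, fold enrichment had a Pearson r of 0.947 on the log2 scale and a Spearman rho of 0.929. That correlation runs across peaks, which are not independent replicates. The sharing of the weakest peaks depended on the overlap rule: requiring 50% of both peaks lowered it to 14.9% in replicate 1 and 13.1% in replicate 2.

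**Figure D1:**
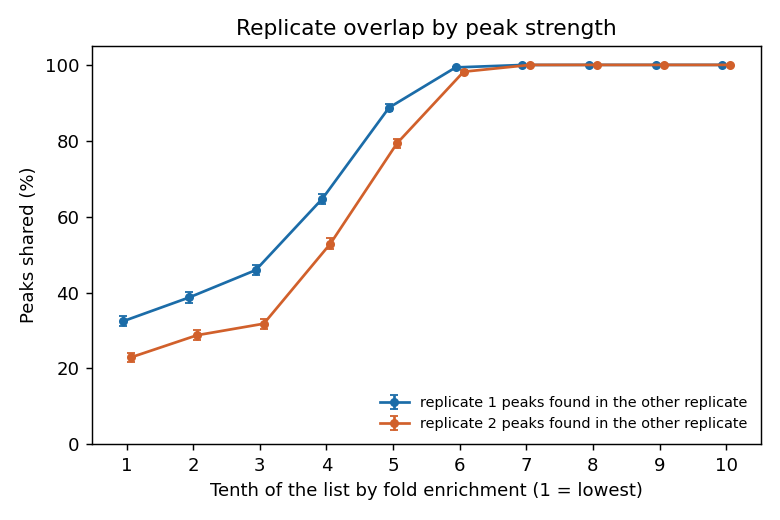
Share of peaks (%) found in the other replicate, in 10 equal bins of each replicate's list ranked by the authors' fold enrichment (1 = lowest); points are shares and bars are 95% Wilson intervals. Sharing starts at 32.4% (replicate 1) and 22.9% (replicate 2) and reaches 100% in bin 10 of both lists.

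The second comparison asked where in the genome the mark lay. Promoters of coding genes carried 39.5% of replicated peak summits (39.0 to 40%; 14273 of 36105), although windows within 1 kb of a coding transcription start site make up 2.08% of the genome. Introns held 27.3% of the summits, exons outside promoters 5.0% and intergenic sequence 28.2%. Promoter peaks were higher and wider than distal peaks. The median fold enrichment was 26.8 at promoters against 4.79 at the 18743 distal peaks, those over 2.5 kb from any coding start, and the median widths were 1983 bp and 661 bp. The promoter share was 25.9% when windows reached only 500 bp from a start.

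Of 21668 coding genes, 14531 (67.1%) had a replicated peak at a promoter. Promoters marked in both replicate lists numbered 14466, or 98.1% of those marked in either, with 94 marked in replicate 1 alone and 183 in replicate 2 alone. Marking followed promoter CpG content. In 10 equal bins of the CpG observed to expected ratio, 1.38% of genes were marked in bin 1, the lowest, 59.1% in bin 4, 91.6% in bin 5 and 99.6% in bin 10. Among genes with a promoter peak in both replicates, the highest fold enrichment in the replicated list was 68.1, at Usp43. Values given here are those of the replicated list, and no replicate 1 peak exceeded 55.2. Usp43, a ubiquitin protease gene on chromosome 11 (67854523 to 67922153), had a domain 2006 ± 103 bp wide (SD, n = 2). Galnt3 and Galnt12, enzymes that start O-linked glycosylation, had 61.8 and 60.3. Specc1 had 61.7, the potassium channel gene Kcnq4 61.5 and the immediate early gene Egr1 60.5. The connexin gene Gjb2 and the Hippo pathway factor Tead4 each had 58.4, the sodium-proton exchanger gene Slc9a2 58.1 and Sned1 57.6.

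**Figure D2:**
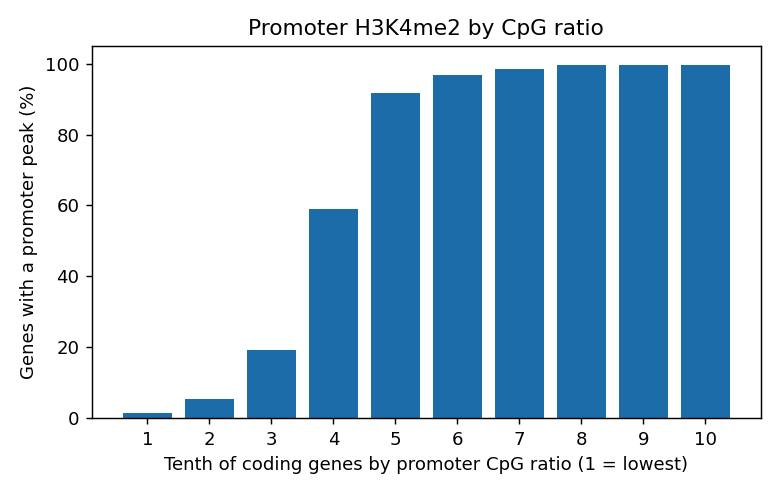
Share of coding genes (%) with a replicated H3K4me2 peak within 1 kb of a coding start, in 10 equal bins of promoter CpG observed to expected ratio (1 = lowest). Bars rise from 1.38% in bin 1 to 99.6% in bin 10.

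The next comparison asked which groups of genes, fixed before the data were examined, carried the mark at their promoters. Every measured member was marked among the hindbrain segment genes (17 of 17), rhombic lip and cerebellar genes (16 of 16), isthmus genes (12 of 12), neural progenitor genes (22 of 22) and pan-neuronal genes (19 of 19). The same held for Hox paralogous groups 1 to 4 (12 of 12) and 5 to 8 (11 of 11), forebrain transcription factors (27 of 27), cell cycle genes (11 of 11) and housekeeping genes (23 of 23). Fewer members were marked in 6 lists: 1 of 18 liver and gut genes, 1 of 14 myeloid genes, 2 of 14 germline and pluripotency genes, 4 of 15 erythroid genes, 5 of 18 muscle and heart genes and 3 of 1134 odorant receptor genes. Against all other coding genes, 10 of the 24 lists had a higher marked share and 6 a lower share at an adjusted p under 0.05 (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). The remaining 8 lists did not pass. By Fisher's exact test these were the Hox groups 9 to 13 (10 of 16, adjusted p = 0.863), hindbrain neuron subtypes (22 of 26, 0.0816), postnatal neuronal genes (10 of 12, 0.430) and glial genes (10 of 14, adjusted p = 1). The same exact test also left out floor plate, roof plate and choroid genes (10 of 14, adjusted p = 1), cranial ganglion and crest genes (11 of 12, 0.151), mesenchyme and meninges genes (13 of 14, 0.0639) and endothelial genes (9 of 15, 0.671).

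Members within each list differed in height. Among the hindbrain segment genes, Mafb and Egr2, the rhombomere factors also called Kreisler and Krox20, had fold enrichments of 41.0 and 40.9, and Epha4, an ephrin receptor of rhombomere borders, had 37.4. In the rhombic lip list, the roof plate factor Lmx1a had 33.5, Barhl2 30.5 and Zic4 29.5. In the isthmus list, the FGF antagonists Spry1 and Spry2 had 36.7 and 32.8 and Pax2 had 22.2. Progenitor promoters were led by Sox9 (40.6), the Notch effector Hes1 (38.7) and the intermediate filament gene Nes (38.5), and neuronal promoters by Rbfox3 (41.6), which encodes the NeuN antigen, Syt1 (35.3) and Rtn1 (34.8). Ccna2 (46.0), Mki67 (37.7) and Plk1 (37.7) led the cell cycle list, and Ubc (46.9), Rab7 (44.3) and Gapdh (39.4) the housekeeping list.

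In other lists some members were marked and others were not. Of the hindbrain neuron subtype genes, the motor neuron factor Isl1 had a fold enrichment of 38.5, the noradrenaline transporter gene Slc6a2 34.6 and the serotonin transporter gene Slc6a4 33.4. Dbh, which makes noradrenaline, had no promoter peak, nor did Nkx2-2 or Phox2b in the replicated list. Nkx2-2 had a peak of fold enrichment 3.83 in replicate 2 alone and Phox2b one of 3.38 in replicate 1 alone. Within 2.5 kb of a start, replicated peaks covered 1360 bp at Nkx2-2 and 1190 bp at Phox2b, against 0 bp at Dbh. The mark thus lay near Nkx2-2 and Phox2b, outside their 1 kb promoter windows. Among postnatal neuronal genes, Arc (40.1), Grin2a (39.6) and Cbln1 (37.4) were marked, while the granule cell gene Gabra6 and the Purkinje cell gene Pcp2 were not. Among glial genes, the oligodendrocyte precursor receptor gene Pdgfra (34.7) and the myelin genes Cnp (33.4) and Mbp (30.5) were marked. Gfap, Mag and Mog were not. The Mbp domain (chromosome 18, 82474489 to 82477710) lay at the annotated 5' end of the gene, 82475146 to 82585637. Its marking therefore does not show that other Mbp transcript starts carry a peak. The morphogen gene Shh (38.2), the ciliary factor Foxj1 (36.1) and Ntn1 (35.4) led the floor plate, roof plate and choroid list, in which Aqp1, Folr1 and Kcne2 lacked a peak. The cranial ganglion list was led by Isl1, Pou4f1 (31.9) and Tfap2a (17.6). Pou4f1 had 32.3 in replicate 1 but 15.8 in replicate 2, below the 16.5 of Tfap2a there.

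Markers of cells that surround or enter the hindbrain were marked in part. Prrx2 (34.9), Foxc1 (29.9) and Col1a2 (27.4) had the highest fold enrichments among mesenchyme genes, and Col3a1 had a peak in replicate 2 alone (3.47). Kdr, the VEGF receptor gene of endothelium, had 45.0, Erg 34.3 and Sox18 26.6, while Cdh5, Emcn and Pecam1 were unmarked. The erythroid genes Klf1 (30.2), Gypa (27.6) and Epor (18.4) were marked and Alas2, Epb42 and Gata1 were not. P2ry12 was the marked myeloid gene, at 3.68, and Aif1, C1qa and C1qb lacked a replicated peak. In the liver and gut list Cdx1 was marked at 7.8, and Afp, Ahsg and Alb were unmarked. Mylpf (36.2), Myod1 (13.3) and Des (12.7) were the highest muscle genes, with Acta1, Ckm and Myf5 unmarked. Dazl (18.1) and Dppa3 (2.69) were the marked germline genes, with Ddx4, Gdf9 and Mael unmarked. Olfr94 (40.4), Olfr658 (10.3) and Olfr1033 (7.19) were the marked odorant receptor genes, and Olfr1, Olfr10 and Olfr1000 were among those unmarked. Beside random lists of the same CpG content, the share marked was at percentile 0 for liver and gut, germline and odorant receptor genes and for Hox groups 9 to 13 (62.5% marked against 95.2%). It was at 99.6 for rhombic lip and pan-neuronal genes, 99.8 for progenitor genes and 99.9 for mesenchyme genes. The other lists with a higher share were marked in full, so their percentile was the highest they could reach and the random lists could not show marking beyond CpG content: hindbrain segment genes (59.1), Hox groups 1 to 4 (95.3) and 5 to 8 (61.6), isthmus (95.3), forebrain (84.5), cell cycle (59.9) and housekeeping genes (68.1). The muscle and heart (11.1), myeloid (5.67) and erythroid (90.4) lists, whose share was lower than that of other genes, lay inside the random range. The lower share of the muscle and heart list did not pass in the pooled list or in replicate 2 alone (44.4% marked, Fisher's exact test, adjusted p = 0.0535 and 0.0618). The higher share of Hox groups 5 to 8 did not pass in replicate 1 alone or at annotated 5' ends (90.9%, Fisher's exact test, adjusted p = 0.146 and 0.148), while the neuron subtype, cranial ganglion and mesenchyme lists passed in the pooled list. Low shares rested on few genes, with 7.14% and 21.4% of germline genes marked in replicates 1 and 2 alone, 14.3% of myeloid genes in replicate 1 and 11.1% of liver and gut genes in replicate 2.

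The width of the H3K4me2 domain, made by joining replicated peaks within 1 kb, differed between the lists, and was greatest over Hox genes. The median marked promoter lay in a domain of 2576 bp, and 169 genes lay in domains of at least 10 kb. The widest domain, 59184 bp on chromosome 11 (96297116 to 96356299), covered the starts of Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6 and measured 57894.5 ± 1503 bp over the replicates (SD, n = 2). The next, 53469 bp on chromosome 6 (52156148 to 52209616), covered Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxa6 and the model 5730596B20Rik. In replicate 2 the Hoxa domain was broken, so that the replicates gave 53362 and 30357 bp at Hoxa2. The POU factor genes Pou3f3 (31665 bp; 31594.5 ± 23.3) and Pou3f2 (22626 bp; 22617 ± 1.41) and the nuclear receptor gene Nr2f2 (28891 bp; 28971 ± 938) followed. Meis2, a Hox cofactor gene, had 26785 bp (25515 ± 843), Zfhx3 25638 bp (26996.5 ± 1996) and Ebf3 23332 bp (23236.5 ± 395). Ptch1, the Hedgehog receptor gene, had 22451 bp (22414.5 ± 30.4), and a domain of 22335 bp (22245 ± 183) lay over the neighbours Lhx1 and Aatf.

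Of the 24 lists, 10 had a median domain width in the upper 2.5% of 10000 random lists matched on promoter CpG ratio, and 2 lay in the lower 2.5%. Hox groups 1 to 4 had a median of 36824 bp against a random median of 2018 bp. Because neighbouring Hox genes share domains and random lists draw genes singly, the width percentiles of the Hox lists overstate the evidence. Hindbrain segment genes had 9688 bp, isthmus genes 7408 bp, rhombic lip genes 7192.5 bp, neural progenitor genes 6998.5 bp, Hox groups 5 to 8 5618 bp, cranial ganglion genes 5442.5 bp and pan-neuronal genes 5422 bp, all at the 100th percentile. Mesenchyme genes had 3259 bp (percentile 99.8) and housekeeping genes 3546 bp (99.3). The replicate medians were 9416.5 ± 16.3 bp for hindbrain segment genes, 6937 ± 16.3 bp for progenitor genes and 31233.8 ± 7880 bp for Hox groups 1 to 4 (SD, n = 2). Hox groups 9 to 13 had a median of 346.5 bp against a random median of 2596.5 bp (percentile 0; 296 and 197 bp in replicates 1 and 2 alone, 116.5 bp for peaks matched in both lists), and germline genes had 0 bp against 1541.5 bp (percentile 0.385). Forebrain transcription factors, at 2475 bp, lay at percentile 47.1, cell cycle genes at 84.9 (3228 bp), hindbrain neuron subtypes at 61.9 (2447 bp; 1951.5 bp at 9.75 in replicate 1 and 3974 bp at 100 in replicate 2) and postnatal neuronal genes at 85.8 (2423 bp). Glial genes lay at 65.4 (1404 bp), floor plate, roof plate and choroid genes at 30.1 (1832.5 bp, but 4135 bp in the pooled list, at percentile 99.99) and endothelial genes at 7.69 (1120 bp, but 696 bp in replicate 2 alone, at percentile 1.73). The erythroid, myeloid, liver and gut, muscle and heart, and odorant receptor lists had a median of 0 bp, as had their random lists. The housekeeping call was lost in replicate 1 and replicate 2 alone (3052 and 2773 bp), the cranial ganglion call without joining peaks (2533 bp, with 15924.5 bp for Hox groups 1 to 4, 4739.5 bp for isthmus and 3598 bp for rhombic lip genes, all still wide), and the Hox groups 5 to 8 call turned at annotated 5' ends (1520 bp, percentile 0.17). The forebrain list was at 4742 bp (percentile 100) with a 3 kb gap and 1752 bp (percentile 0.395) without joining; a 3 kb gap also raised the neuron subtype (7954 bp) and floor plate, roof plate and choroid lists (6437.5 bp).

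**Figure D3:**
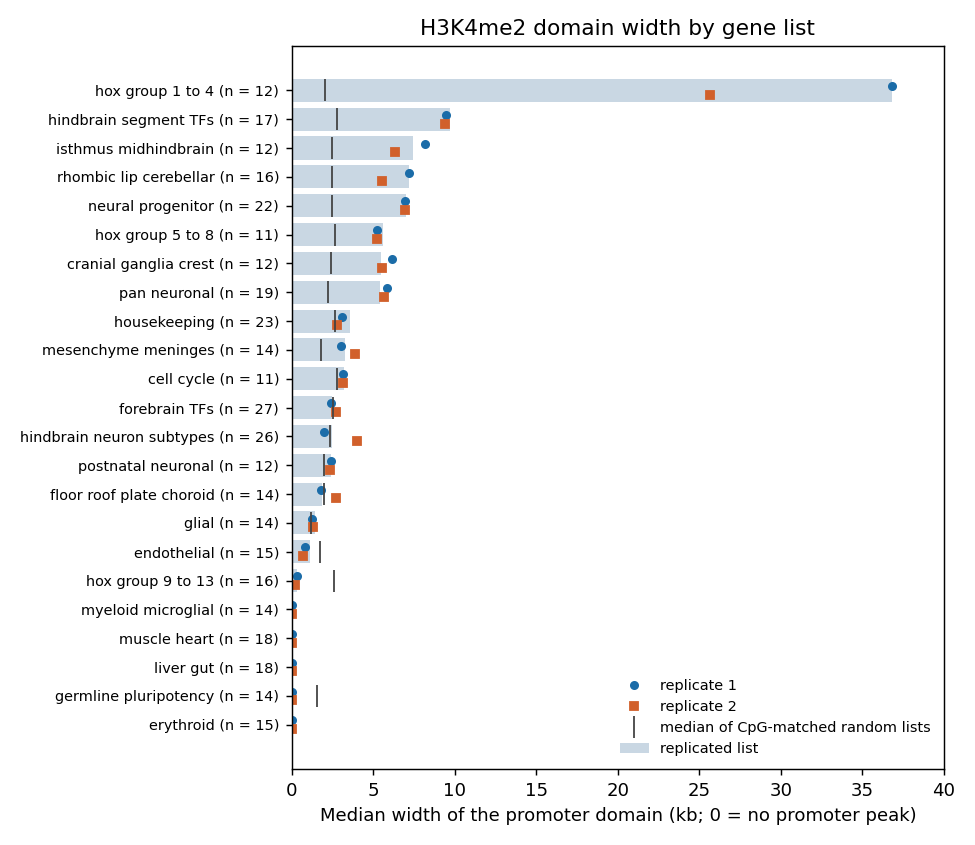
Median width (kb) of the H3K4me2 domain at the promoter for each gene list, counting unmarked genes as 0; bars are the replicated list, circles and squares the 2 replicates, and vertical ticks the median of CpG-matched random lists; the odorant receptor list, at 0, is left out. Hox groups 1 to 4 stand at 36.8 kb and Hox groups 9 to 13 lie below their random lists.

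Hox genes are ordered along their clusters as they are along the body axis, with paralogous groups 1 to 4 used in the hindbrain and groups 9 to 13 in the posterior trunk. Coverage fell from groups 1 to 4 to groups 9 to 13 on average, with exceptions at both ends. Hoxb3, Hoxb4, Hoxb5 and Hoxa2 were among those with all 5001 bp of the window around a start site covered by replicated peaks, and Hoxa9, Hoxc9, Hoxc11 and Hoxc12 were among those with 0 bp. Groups 1 to 4 averaged 4103 ± 1529 bp covered (SD over genes, n = 12), groups 5 to 8 2894 ± 1514 bp (n = 11) and groups 9 to 13 555 ± 541 bp (n = 16). The difference between the first and last groups was 3548 bp, with p = 1e-05 in a two-sided permutation test, the smallest that 100000 resamples can give. Both replicates showed it, with means of 3966 and 455 bp in replicate 1 and 4098 and 454 bp in replicate 2. Of the genes in groups 9 to 13, 5 of 16 had no covered base. Neighbouring Hox genes share domains and are not independent, so the permutation p overstates the evidence. In groups 1 to 4, Hoxa3 stood out with 1270 bp, since its transcript in the annotation used starts upstream of Hoxa6; Hoxb1 (1639 bp) and Hoxd1 (1831 bp) were also low. At the other end, some group 13 genes exceeded genes before them in the cluster: Hoxa13 had 1681 bp against 1015 bp at Hoxa7 and 233 bp at Hoxa10, Hoxc13 963 bp against 333 bp at Hoxc8, and Hoxd13 1016 bp against 543 bp at Hoxd10, but Hoxb13 had 221 bp against 699 bp at Hoxb9. These genes were singled out after their values were seen.

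**Figure D4:**
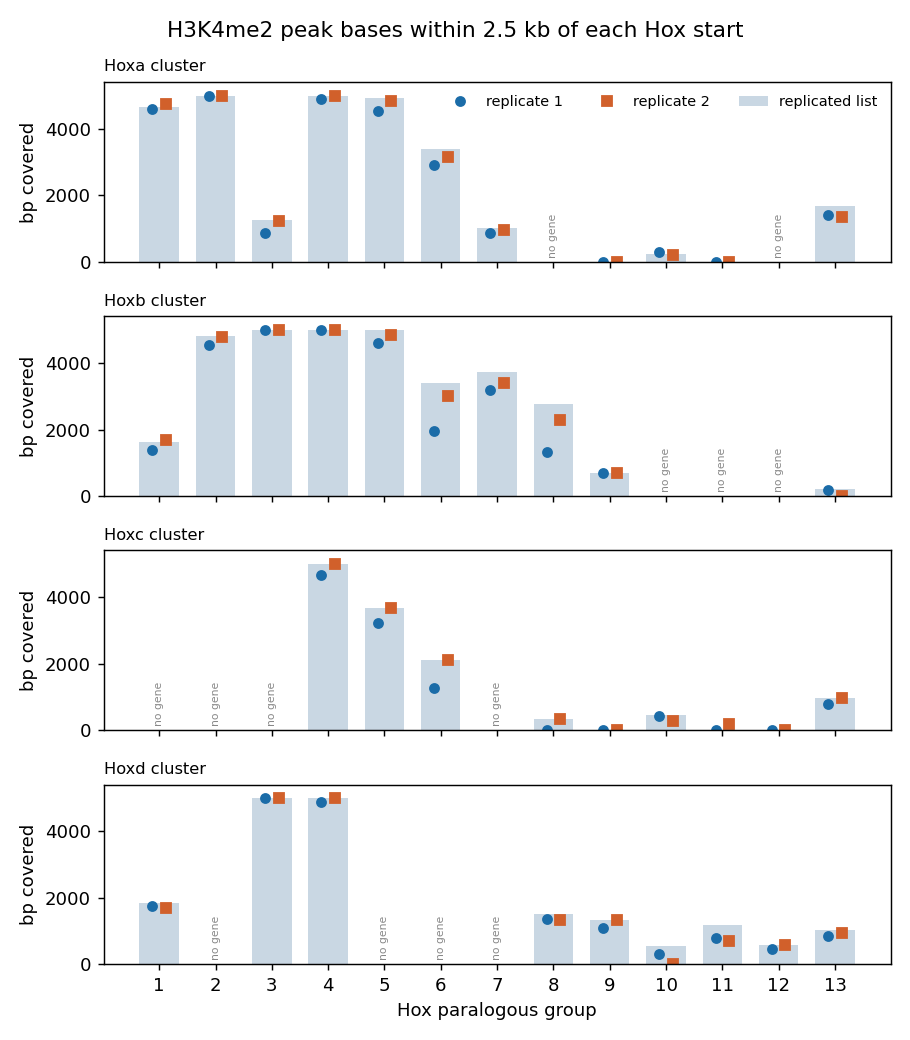
Bases (bp) covered by H3K4me2 peaks within 2.5 kb of the best covered start of each Hox gene, by paralogous group (1 to 13) in the 4 clusters; bars are the replicated list, circles replicate 1 and squares replicate 2. Groups 1 to 4 average 4103 bp and groups 9 to 13 average 555 bp.

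Transcription factors of the forebrain gave a within-study contrast to the hindbrain segment, isthmus and rhombic lip lists. The hindbrain neuron subtype list was not part of this contrast. Its median width, 2447 bp (1951.5 and 3974 bp in replicates 1 and 2), was near the 2475 bp of the forebrain list. Wide domains were not limited to hindbrain lists either, with medians of 6998.5 bp for progenitor, 5442.5 bp for cranial ganglion and 5422 bp for pan-neuronal genes. The promoters of Dlx2 (fold enrichment 44.6), Satb2 (39.8) and Emx1 (28), regulators of forebrain interneurons and cortex, were marked in hindbrain, as were all 27 members of the list. Their domains were narrower on average than those of the pooled hindbrain segment, isthmus and rhombic lip genes, with overlap between the sets. Dlx2 had a domain of 7405 bp (5707 ± 1932 over the replicates; SD, n = 2) and Emx1 one of 2612 bp (2588 ± 197). Of the hindbrain genes, Zic4 had 22308 bp (23032 ± 935), the widest of the rhombic lip list. In the replicated list Mafb (5734 bp), Spry1 (5022 bp), Egr2 (4354 bp), Lmx1a (3256 bp) and Barhl2 (2617 bp) were narrower than Dlx2. The same order held in replicate 2, where Dlx2 had 7073 bp. In replicate 1 Dlx2 had 4341 bp and was narrower than Mafb (5690 bp) and Spry1 (6096 bp). Lmx1a had 2893 and 1488 bp in replicates 1 and 2. Mean width was 9428 ± 6570 bp in the hindbrain lists (SD over genes, n = 45) and 3308 ± 3004 bp in the forebrain list (n = 27). The difference of 6120 bp had p = 4e-05 in a two-sided permutation test, and was 6093 bp in replicate 1 and 5776 bp in replicate 2. On highest fold enrichment the lists averaged 23.0 ± 10.1 and 16.9 ± 11.1 (permutation p = 0.022), and without joining peaks the difference in width was 3900 bp (permutation p = 0.00026).

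The comparison of distal peaks counted those within 100 kb of each gene's 5' end. Of the 10 genes with the highest counts, 6 lay in a region of chromosome 13 that holds histone genes. These were Btn2a2 (25 distal peaks), Btn1a1 (23), Abt1, Hist1h4h, Pom121l2 and Zfp184 (22 each). The rest lay away from chromosome 13. They were Pax2 (24), a regulator of the isthmus and of inhibitory neurons, Gins2 (23), Irf2bpl and Ahdc1 (22 each). Isthmus genes had a median of 9 distal peaks, neural progenitor genes 7.5, rhombic lip and cranial ganglion genes 6.5 each and hindbrain neuron subtypes 5, against 2 in their CpG-matched random lists. In all, 11 of the 24 lists lay in the upper 2.5% of random lists. Also among them were Hox groups 1 to 4 and 9 to 13, with 4.5 each. So were hindbrain segment genes, forebrain factors, glial genes and muscle and heart genes, with 4 each. High counts were thus not limited to hindbrain genes. Neighbouring Hox genes share much of their 100 kb windows, with 7 distal peaks at every Hoxa gene of groups 9 to 13. Random lists draw genes singly, so the distal percentiles of the Hox lists overstate the evidence. Those below that level were Hox groups 5 to 8 (median 4, percentile 96.4), pan-neuronal (3, 92.1), postnatal neuronal (1.5, 43.3), floor plate, roof plate and choroid (3, 93.2), cell cycle (2, 54.5) and housekeeping genes (3, 91.5). Mesenchyme (3, 95.1), endothelial (3, 93.4), erythroid (1, 76.2), myeloid (2, 91.3), liver and gut (2.5, 97.0), germline (2, 70.2) and odorant receptor genes (0, 18.7) were also below it. The counts assign no element to a gene, and 8 lists passed with a 500 kb window but 16 in the pooled list, in replicate 2 alone and with a 50 kb window. With the 500 kb window Hox groups 1 to 4 (percentile 97.0), rhombic lip (91.7), neuron subtype (96.2), forebrain (81.6), glial (96.2) and cranial ganglion genes (96.2) no longer passed, nor did hindbrain segment genes for peaks matched in both lists (94.8). Medians in replicates 1 and 2 alone were 15 and 11 for Hox groups 5 to 8, both in the upper 2.5%, 10.5 and 10 for groups 1 to 4, 9 and 7 for groups 9 to 13, 10 in each for cranial ganglion genes, 8 and 7.5 for neuron subtypes, 6 in each for mesenchyme, 6 and 4.5 for floor plate, roof plate and choroid, 3 and 5 for endothelial and for myeloid, and 1 and 3 for erythroid genes. By these medians mesenchyme genes passed in both replicates and floor plate, roof plate and choroid genes in replicate 1. Endothelial, myeloid and erythroid genes passed in replicate 2. Odorant receptor genes, with a median of 0, fell into the lower 2.5% in replicates 1 and 2 alone (percentiles 1.12 and 0.23). They did so in the pooled list as well (0.005).

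The last comparison asked which of 15 fixed consensus motifs were more frequent within the central 300 bp of distal peaks than in GC-matched windows nearby, using 16627 pairs. The homeodomain core TAATTA was in 7.52% of peaks and 3.78% of windows (odds ratio 2.07, 95% interval 1.88 to 2.29; Fisher's exact test, adjusted p = 4.61e-49), and the E-box CAGCTG, bound by proneural factors, in 23.9% and 19.5% (1.30, 1.23 to 1.37; adjusted p = 6.29e-22). The POU octamer ATGCAAAT had an odds ratio of 2.45 (2.05 to 2.93), the SOX motif 1.86 (1.60 to 2.16) and the RFX motif, of ciliogenic factors, 4.54 (2.94 to 7.01) on 113 peaks and 25 windows. CTCF had 3.04 (2.23 to 4.14), MEF2 1.67 (1.10 to 2.52) and MEIS 1.17 (1.11 to 1.23). These 8 motifs passed at an adjusted p under 0.05. The E-box CAGATG (odds ratio 0.972, adjusted p = 0.350), the HOX-PBX site (1.03, 0.918), NFI (2.25, 0.350), ETS (1.67, 0.167), GATA (0.949, 0.491), HNF4 (1.00, adjusted p = 1) and AP1 (0.907, 0.0991) did not pass the exact test. In the central 150 bp the CTCF odds ratio turned to 0.52 (Fisher's exact test, adjusted p = 0.136), MEF2 did not pass in replicate 1 alone (1.41, adjusted p = 0.0863), and RFX had 2.83 at a −log10 q of at least 5. NFI, on 9 peaks and 4 windows, and ETS passed as enriched under some alternatives (15 for NFI in replicate 1 alone, 2.5 for ETS in replicate 2 alone). AP1 passed as depleted in either replicate alone (0.866 and 0.902). Control windows were drawn anew for each alternative, so such changes may come from the draw.

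**Figure D5:**
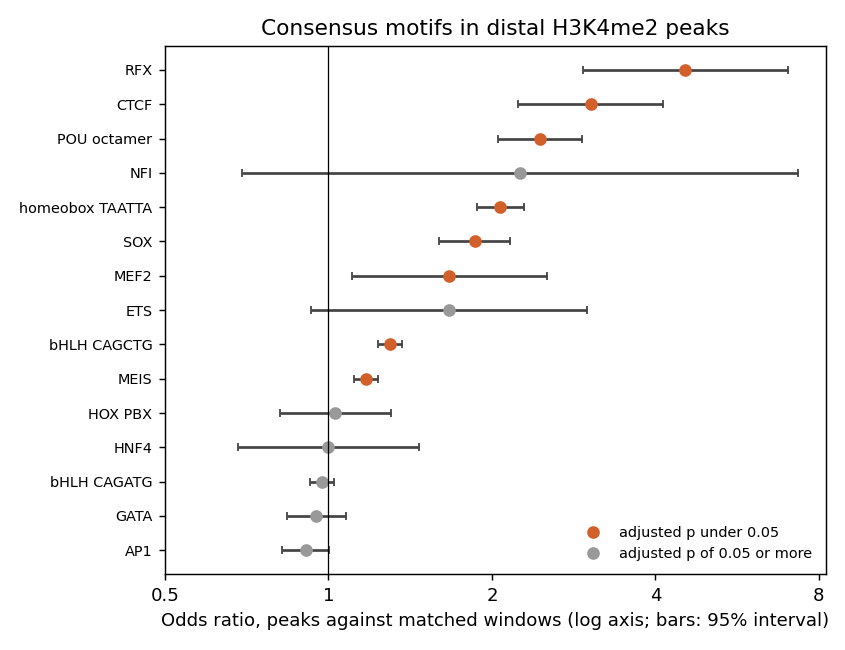
Odds ratio (log axis) of each fixed consensus in the central 300 bp of distal H3K4me2 peaks against GC-matched windows; points are odds ratios, bars 95% intervals, and colour marks an adjusted p under 0.05. RFX (4.54), CTCF (3.04), the POU octamer (2.45) and TAATTA (2.07) stand above 1, and GATA, HNF4 and AP1 do not.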

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

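Peaks outside the chromosomes compared in the report exceeded the limit that a count of 0 allows, 3 counts. The replicated list held 8 peaks on chromosome Y. Of these, 1 lay at the start of Kdm5d (fold enrichment 5.84), 1 at Eif2s3y (6.59), 2 at Uty (5.84 and 3.29) and 2 at Ddx3y (7.04 and 3.59), and the other 2 were away from annotated starts. The pooled embryos were of both sexes. The replicated list also held 12 peaks on unplaced or unlocalised contigs, with a highest fold enrichment of 11.7. No explanation was tested for either set.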

How the results depend on the processing

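The matching in both replicate lists, the comprehensive transcripts, the 5' ends for the Hox difference and the counting of each domain once were chosen after the results were seen; the other alternatives, 5' ends for the gene lists included, were fixed before. No paired analysis of the samples was possible, because they form a single group and no test compares them. The motif comparison drew a matched window for each peak, but its exact test and intervals did not use that pairing. With 2 replicates, leaving out either leaves the list of the other. Of the values that answer a comparison, 644 recomputed values kept their call or stayed near the reported value, 28 moved by more than their counting error, 29 gained a call, 13 lost it and 5 turned. Distal counts of single lists are not in that tally: 31 gained a call and 7 lost it; the cause was not tested for any of these. Unknown depth limits the weak peaks most, since the lists cannot show whether a missing peak was absent or missed.

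The counts by list and the group differences kept their direction under every alternative. Lists with a higher marked share numbered 9 to 13, with a lower share 5 to 6, with wide domains 8 to 13, with narrow domains 2 to 3 and with many distal peaks 8 to 16. Enriched motifs numbered 7 to 11. The Hox difference ran from 2832 to 7045 bp in covered bases (permutation p = 1e-05 throughout), and the hindbrain against forebrain difference from 3900 to 6573 bp (permutation p from 1e-05 to 0.00028), or a fold enrichment of 6.07 (permutation p = 0.022).

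Of replicate 1 peaks, 80.9% were shared at an overlap of at least 1 bp, 62.1% at 50% of both peaks, and 81.1% and 93.9% at a −log10 q of at least 2 and 5. For replicate 2 these were 75%, 59.9996%, 74.6% and 86.9%. In bin 1 of fold enrichment they were 42.2%, 14.9%, 37.7% and 62.7% (replicate 1) and 30.9%, 13.1%, 25.1% and 36.6% (replicate 2), and at 50% of both peaks bin 10 had 97.2% and 97.6%. On −log10 p, Pearson r was 0.965 and Spearman rho 0.959, and at a −log10 q of at least 2 rho was 0.927. The promoter share of summits was 29.3% in the pooled list, 32.5% to 34.4% without either replicate, 43.7% at a −log10 q of at least 5, 43% for peaks matched in both replicate lists, and 25.9% and 46% with windows of 500 bp and 2 kb.

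Marked shares that changed their call were, for Hox groups 5 to 8, 90.9% matched in both lists and at 5' ends, and 90.9% to 100% without either replicate. The neuron subtype share was 92.3% in the pooled list and with a 2 kb window, and 88.5% without either replicate. Both alternatives gave 100% for the cranial ganglion list (91.7% to 100% without either replicate) and the mesenchyme list. The muscle and heart share was 44.4% in the pooled list and 27.8% to 44.4% without either replicate.

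Median widths that changed their call were 1520 bp for Hox groups 5 to 8 at 5' ends, and for neuron subtypes 4773 bp in the pooled list, 7954 bp with a 3 kb gap and 1951.5 to 3974 bp without either replicate. The forebrain list had 1752 bp without joining and 4742 bp with a 3 kb gap, and floor plate, roof plate and choroid genes 4135 bp in the pooled list and 6437.5 bp with a 3 kb gap. Cranial ganglion genes had 2533 bp without joining. Housekeeping genes had 2755 bp at a −log10 q of at least 5 and matched in both lists, 2699 bp at 5' ends, 2527 bp without joining and 2773 to 3052 bp without either replicate. Endothelial genes had 696 to 819 bp without either replicate.

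Each motif alternative drew its own random control windows, so a changed call may come from the draw and not from the setting. A −log10 q minimum of 2 kept 99.5% of replicated peaks, so the peaks themselves hardly changed there. Odds ratios that changed their call were 1.35 for HOX-PBX at a −log10 q of at least 2, and 0.52 for CTCF in the central 150 bp. NFI had 10.0055 at a −log10 q of at least 2, 6.5 around peak midpoints and 2.1 to 15 without either replicate. ETS had 1.88 in the pooled list, 2.5 at a −log10 q of at least 2, 3.0 matched in both lists, 2.47 at midpoints and 1.52 to 2.5 without either replicate. AP1 had 0.859 in the pooled list, 0.842 and 0.855 at a −log10 q of at least 2 and 5, 0.791 at midpoints and 0.866 to 0.902 without either replicate, and MEF2 had 1.41, its call lost, to 1.62 without either replicate.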

Other observations

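Of the tests below, those on forebrain promoters and the interval within 75 bp of the summit were chosen after the results were seen. The other tests were set out before the values they measure were seen.

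Of 2196 annotated microRNA genes, 277 (12.6%) lay inside an H3K4me2 domain. All 3 copies of the neural microRNA miR-9 were among the 4 widest ranks: Mir9-2 in 29695 bp on chromosome 13 (83713171 to 83742865), Mir9-3 in 25907 bp on chromosome 7 (79495774 to 79521680) and Mir9-1 in 25556 bp on chromosome 3 (88197906 to 88223461). The widest, 59184 bp, held Mir10a inside the Hoxb cluster. The 3 copies of the neuronal miR-124 lay in 17042 bp (Mir124a-2), 10485 bp (Mir124a-1) and 10302 bp (Mir124a-3). Among 10382 long noncoding genes over 2.5 kb from a coding start, 1381 (13.3%) had a promoter peak, and the widest outside the Hox clusters included Pantr2 beside Pou3f3 (31665 bp) and C130071C03Rik (29695 bp), which shares the domain of Mir9-2. These genes were picked out after the ranking was seen, and no list of neural microRNAs was tested.

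Families were also taken from gene symbols, without any prior list. Of 340 symbol prefixes with at least 8 coding members, 28 had a median domain width in the upper 2.5% of 1000 CpG-matched random lists and 17 in the lower 2.5%. No adjustment was made for the 340 prefixes, some of which fall in either tail by chance. Genes of 1 cluster, such as Hoxb, can share domains while random lists draw genes singly. The percentiles of clustered families thus overstate the evidence. The wide families included Hoxb, Lhx, Pax and Sox genes, the chromobox Cbx genes (5975.5 bp against 3047.5 bp), the Arid chromatin genes (5300.5 against 2730.5 bp), the Wnt receptor Fzd genes (5301.5 against 2825 bp), the Pcdh protocadherins (7938 against 2347.75 bp) and the Sema guidance genes (3864.5 against 2311 bp). The narrow families were mixed. Nkx (1275.5 against 2382.25 bp), Hoxd (1321 against 2680 bp), Hoxc (460 against 2149 bp), Pcdha (0 against 2441.5 bp), Ddx, Ttll and Entpd lay at percentile 0, and Acot, Srp, Mrps, Taf, Slc, Cfap, Nol, Coq, Cox and Spag made up the rest. In replicates 1 and 2 the Fzd medians were 5627.5 and 5248 bp and the Cbx medians 4999 and 4988 bp, but the Pax medians 6687 and 3888 bp, against 6729 bp in the replicated list.

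Some genes departed from the relation with CpG content. Of 10834 genes in the upper 5 of 10 bins of CpG ratio, 119 had no promoter peak in the replicated list or either replicate list. The largest group was 41 gene models with Gm numbers. The others included 14 entries of the clustered protocadherin genes, 3 Hox genes (Hoxa9, Hoxa11 and Hoxc12) and 7 histone genes. Some of the unmarked genes had the same CpG ratio as another, such as Entpd4 and Entpd4b (0.804 each). The lists cannot show whether reads could be placed at near-identical copies, so a missing peak there may not mean an absent mark. This limit also applies to the narrow Entpd family, which includes both genes. In the lowest 2 bins, 130 of 4334 genes were marked in all 3 lists, led by the histone demethylase gene Kdm6b (fold enrichment 47.9, domain 13672 bp), Gp5 (47.0) and Ltbp3 (45.1). CpG content was measured within 500 bp of a start but marking within 1 kb. A peak counted here thus need not lie at the CpG-poor start, and whether it belonged to a neighbouring promoter was not tested. Across 9083 marked genes with domains under 3 kb, CpG ratio and fold enrichment had a Spearman rho of 0.310, across genes.

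Fold enrichment ranked the gene lists differently from width. Forebrain factors (median 15.6 against 29.4 in CpG-matched marked genes), hindbrain neuron subtypes (18.2 against 29.3) and Hox groups 5 to 8 (9.85 against 29.6) and 9 to 13 (4.64 against 29.2) were at percentile 0. Cranial ganglion (16.3 against 28.9), rhombic lip (20.8 against 29.1), isthmus (19 against 28.3) and Hox groups 1 to 4 (18.3 against 26.7) were below percentile 1, so low values were shared by wide and narrow lists. Neighbouring Hox genes were not independent here either. Hoxb3, Hoxb4, Hoxb5 and Hoxb6 had the same fold enrichment in the replicated list, 18.3, although Hoxb6 had 3.54 and 4.33 in replicates 1 and 2. The fold percentiles of the Hox lists thus overstate the evidence. Hindbrain segment genes (29.5, percentile 41.9) and housekeeping genes (29.3, percentile 38.5) were inside the random range. On chromosome X, 51.3% of 948 coding genes were marked, against 67.8% of 20720 on autosomes, shares that were not matched on CpG content. The median fold enrichment of marked promoters on X was 17.1, against 28 in CpG-matched autosomal sets. The 1000 draws of those sets ranged from 26.2 to 29.4. No cause of either difference was tested.

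The marking of all 27 forebrain factors in hindbrain was weighed against their promoter class. Their marked share lay at percentile 84.5 of random lists matched on CpG ratio, which is the highest a list of these genes can reach, so the test could not go against CpG content and leaves it open. Forebrain tissue carried over in the dissection stays open too: the median forebrain domain lay at percentile 55.2 in replicate 1 and 83.2 in replicate 2, inside the random range, and marking near saturation leaves little room for a small share of other tissue to show. The design holds no forebrain sample, so no biological explanation was tested.

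The cluster of distal peaks near the histone genes of chromosome 13 (21855150 to 23587365) was compared with other annotation. Of the 48 distal peaks within 100 kb of the 6 genes there, 38 (79.2%) lay within 500 bp of an annotated transfer RNA gene, against 0.790% of all distal peaks. Only 8 (16.7%) lay within 1 kb of the start of another GENCODE transcript, a set searched apart from the transfer RNA genes. That share was below the 25% set as the bound and near the 17.4% of all distal peaks. It argues against the promoters of those annotated transcripts, but cannot speak to unannotated promoters. A candidate explanation is thus that these peaks mark transfer RNA genes, and 250 of 403 such genes (62.0%) had a replicated peak within 500 bp.

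Against control windows chosen anew to match over a wider span, the odds ratio of the CTCF consensus was 1.07 (95% interval 0.527 to 2.16) within 75 bp of the summit, where the narrower matching gave 0.52, 4.88 (3.44 to 6.93) from 75 to 150 bp and 10.8 (8.0 to 14.6) from 150 to 300 bp, a band outside the windows searched before. Too few matches near the summit was argued against, since the upper limit of 2.16 lies below 4.88. The values are consistent with a summit that lies on a nucleosome beside the bound site. RFX had 2.67, 4.46 and 5.17 in the 3 bands, with an inner interval of 1.47 to 4.84 that holds the next value, MEF2 had 1.29, 2.34 and 2.05, TAATTA 1.67, 1.69 and 1.93 and CAGCTG 1.41, 1.21 and 1.08. GC was not balanced band by band, with 53.2% in peaks and 50.2% in controls within 75 bp, 50.9% and 50% in the next band and 48.3% and 49.6% in the outer band.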
